A study of Homo sapiens with 2 samples.

How the data were processed

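The data are 2 Illumina bead arrays of total RNA, 1 from wild-type A4573 cells and 1 from radiation-adapted A4573 cells. Per the labels' protocols, RNA was extracted with Trizol, its quality was checked on a Bioanalyzer, and biotin-labelled cRNA was made with the Illumina TotalPrep kit. Groups were taken from the cell line label of each sample, and the number 4 Gy from the description of the adapted sample.

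The deposited summary table gives for each probe an intensity and a detection p-value per array. Per the file headers, the intensity is the average signal of a probe before normalisation, and its lowest values (100 and 102) show that no background had been subtracted. The detection p-value, deposited by the authors beside each intensity, compares the probe with the negative controls of the array in steps of 0.0013, and small values went with high intensity. Bead numbers and bead SDs were not used here, and the scanner software and its version are not given in the sources used here. The authors' second table holds processed intensity values on a linear scale. Its columns rank the probes as the summary intensity of the same array does (Spearman rho 1.00 over probes, against 0.861 with the other array), which settles their direction. Each column has a median of 10.6, 27.7% of the values lie below 0, and the sorted columns differ by at most 0.5, so the values are background-subtracted and quantile-normalised. How the authors did this is not given in the sources used here, and the common distribution is not the mean of these 2 arrays.

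Probes were named from the given platform annotation, with symbols checked by gene ID against the RefSeq table of assembly GRCh38.p14, which was used for names, chromosomes and the order of genes alone. Of 47323 probes, 30113 had 1 gene symbol, 8 had several and 17202 were not listed and stayed unnamed; 30074 were found in RefSeq by gene ID. They named 20046 genes. Y-linked genes and others used to tell sex were left out.

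Main values were made from the summary intensities with neqc of limma 3.58.1 in R 4.3.3, which fits a normal-exponential background from the detection p, adds an offset of 16, quantile-normalises and takes log2. A probe counted as detected at a detection p of at most 0.01, and a gene entered with a probe detected in at least 1 array, giving 11287 genes. Of these, 9824 were detected in both arrays, 983 in the wild-type array alone, 451 in the adapted array alone, and 29 by different probes in the 2 arrays. The probe with the highest mean log2 value stood for its gene; among 2326 genes with at least 2 probes detected in both arrays, 647 had probes of differing sign. For a gene detected in 1 array only, the difference is a bound: the bright value against the higher of the dim probe's own value and the lowest value of any detected probe on the dim array. Quantile normalisation gives both arrays the same overall distribution and so removes any difference in total RNA, and the offset draws the differences of dim probes towards 0.

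With 1 array per group no test was run, and no p-value or SE between samples is given; the number of arrays limits the precision. Genes were counted by size, at 2-fold, and list members at 1.5-fold. For each of 40 gene lists (985 distinct genes, 918 with a named probe) the median difference was set against medians of 10000 random lists of the same size matched on mean expression in 20 bins, and a list was called apart outside the middle 95%. List medians, intervals and percentiles use the measured differences of all members, also of genes detected in 1 array only. Member counts use the bounds, and medians with bounds are given beside. Intervals come from 2000 bootstrap draws over members and describe the choice of genes, not the error between cultures. Lists share some members, and were written from general knowledge. The scatter between the 2 brightest probes of a gene, divided by the square root of 2, gave the SD per probe. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

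Named genes were the 10 highest and 10 lowest differences among genes detected in both arrays with all probes of one sign, the 5 largest bounds in each direction, up to 4 members of each list with the largest differences and any member with a bound of at least 2-fold, and CD99, FLI1, NKX2-2, NR0B1 and STEAP1. The text gives a part of those chosen by list. NR0B1 was not analysed here, and the result of 1 list is not reported here. The design, lists, rule for names and processing alternatives were chosen before the data were examined; the runs and windows of neighbouring genes, the alternatives for both and for chromosome 11, and the genes said to be chosen later came after.

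The steps were tested on simulated wild-type and adapted arrays of 12147 genes, both drawn from the values of the measured wild-type array. In the simulated adapted array 200 genes were changed, and the noise SD was 0.2 on the log2 scale in each array. Every changed gene had a detected probe well above background, so the shares found do not cover dim genes. The scatter between probes of one gene then gave an SD of 0.31 per probe in the simulated arrays, against 0.28 in the measured ones. All of 50 genes raised 4-fold and all of 50 lowered to 0.25 were found at least 2-fold apart the right way, as were 80.0% of those raised 2.5-fold and 88.0% of those lowered to 0.4, and 0.268% of unchanged genes passed the size in either direction. Of 100 unchanged lists 4 lay outside the middle 95%, and all 20 lists with 15 of 25 members raised lay above it. These lists were random draws with independent noise. They check the computation alone, and not lists whose members vary together or differences between cultures.

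Alternatives were no background correction, an offset of 50, median scaling in place of the quantile step, the authors' processed values (those under 1 set to 1), a detection p of 0.05, no detection filter, the mean over probes of a gene, a 1.5-fold size, list members detected in both arrays only, and random lists not matched on expression.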

Results

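Gene expression was measured in A4573, an established Ewing sarcoma cell line, as the parental wild-type culture and as a radiation-adapted derivative. Ewing sarcoma is a tumour of bone and soft tissue driven by a fusion transcription factor, most often EWSR1-FLI1. The adapted sample carries the label 4 Gy, and the labels give no schedule of irradiation and no interval before harvest. Total RNA from each culture was hybridised to 1 Illumina bead array, so the design holds 1 array per group and the comparison has no replicate check. Each array reported an intensity and a detection p for 47323 probes. At a detection p of at most 0.01, 17903 probes (37.8%) were detected in the wild-type array and 16712 (35.3%) in the adapted array. Median intensities were 139 and 140, and the dimmest detected probes read 152 and 158. Across 15670 probes detected in both arrays, the normalised log2 values correlated at r = 0.964, a value taken across probes, which are not replicates.

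The comparison asks how the transcriptome of the adapted cells differed from that of the wild-type cells. Differences are given as log2 adapted minus log2 wild-type. Genes of the mitotic cycle were higher in the adapted array, including the centromeric histone CENPA (2.30) and the mitotic kinesins KIF20A (2.14) and KIF4A (2.23). Chemokine and other NF-kB target genes were much lower, with CCL20, a lymphocyte-attracting chemokine, at -5.89, or 59.4-fold lower (-4.71 without background correction). The cytokine IL32 (-5.09), the immediate early transcription factor EGR1 (-4.02) and the matrix protein fibrillin 2, FBN2 (-3.38), were also far lower. Without background correction these values were closer to 0, at 1.27 for CENPA, 1.19 for KIF20A, 1.39 for KIF4A, -3.74 for IL32, -2.71 for EGR1 and -2.06 for FBN2. Genes of DNA repair by homologous recombination, glycolysis and cholesterol synthesis were higher as groups, and genes of antigen presentation, interferon response, extracellular matrix and adhesion were lower as groups.

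Of 9824 genes detected in both arrays, 276 (2.81%) were at least 2-fold higher in the adapted array and 407 (4.14%) at least 2-fold lower. Without background correction these counts were 76 and 153, and in the authors' processed values 463 and 537. All 161 named genes at least 1.5-fold apart had smaller differences without background correction, by a median of 1.49 times, and 128 stayed at least 1.5-fold apart. None changed sign, but quantile normalisation of the same ranks fixes the sign of a probe in advance. The order of genes by size is that of the main normalisation. Differences of at least 4-fold were found for 11 higher and 53 lower genes. The median difference was 0.04, with quartiles of -0.29 and 0.35. Besides those named above, the genes furthest below their wild-type level were CRABP2 (-3.25), a retinoic acid binding protein, FEZ1 (-3.14), the alkaline phosphatase ALPL (-3.12), TPST1 (-3.03), EFEMP2 (-2.93) and IER3 (-2.86). The brain-type aldolase ALDOC was the furthest above (3.12, or 8.67-fold), followed by MBD3L5 (2.97), the kappa-casein gene CSN3 (2.42), SNTB1 (2.39), the mTOR inhibitor DEPTOR (2.31), CDCA3 (2.24) and SEMA5B (2.15). MBD3L5 belongs to a family of nearly identical copies that a probe may not tell apart, so its value is uncertain.

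**Figure D1:**
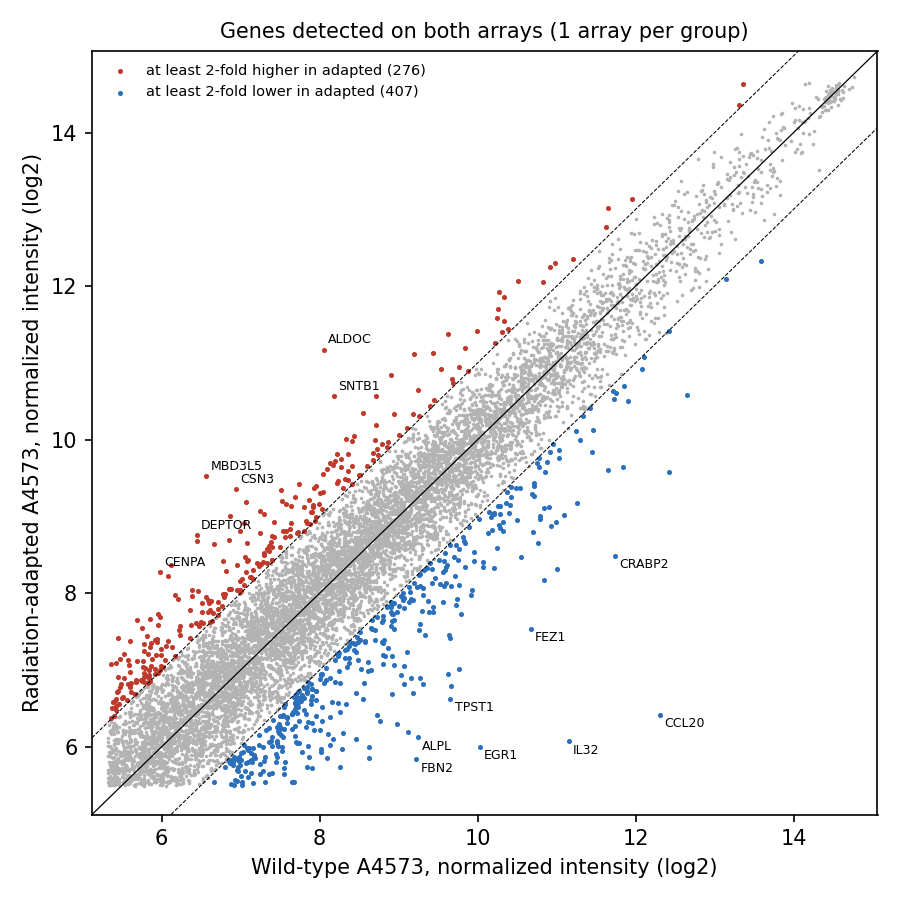
Normalised intensity (log2) of each gene detected on both arrays, with wild-type A4573 on the x axis and radiation-adapted A4573 on the y axis (1 array per group); the solid line marks equality and the dashed lines 2-fold differences. The 276 genes at least 2-fold higher in the adapted array are red and the 407 at least 2-fold lower are blue, and CCL20 and IL32 lie furthest below the line.

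A further 983 genes were detected in the wild-type array alone and 451 in the adapted array alone, and their differences are bounds. The bound reached 2-fold for 88 genes lower and 33 genes higher in the adapted array. Tryptophan dioxygenase, TDO2, was at least 39.3-fold lower, the neutrophil chemokine CXCL8 at least 17.9-fold, the ubiquitin-like modifier UBD at least 17.5-fold, the monocyte chemokine CCL2 at least 17.0-fold and the AP-1 component FOS at least 9.64-fold, each not detected in the adapted array. In the other direction, the nuclease DNASE1L3 was at least 15.8-fold higher, the collagen COL14A1 at least 9.42-fold, the replication fork factor RADX at least 6.20-fold, SCARNA18 at least 3.80-fold and the casein CSN1S1 at least 3.64-fold, each not detected in the wild-type array. All bounds given here hold for the main normalisation, and these were smaller without background correction, at 11.9-fold for TDO2, 5.82-fold for CXCL8, 5.70-fold for UBD, 5.56-fold for CCL2 and 3.47-fold for FOS. In the other direction they were then 4.86-fold for DNASE1L3, 3.20-fold for COL14A1 and 2.36-fold for RADX, and under 2-fold for SCARNA18 (1.74) and CSN1S1 (1.69). With the mean over probes, TDO2 was at least 12.4-fold and CXCL8 at least 10.8-fold lower. Not detected here means a detection p above 0.01, and some probes lay close to that cut. In the adapted array the detection p was 0.0156 for TDO2, 0.0117 for CCL2 and 0.026 for FOS. In the wild-type array it was 0.0169 for COL14A1 and 0.0143 for CSN1S1. With the limit at 0.05, TDO2, CCL2, FOS, COL14A1 and CSN1S1 counted as detected in both arrays, so their differences were then not bounds.

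The 40 gene lists fixed in advance were compared with random lists of matched expression. Medians of 8 lists lay above the middle 95% of random-list medians and those of 12 lists below it, and these percentiles describe this pair of arrays only. All 20 stayed apart without background correction, but 14 of the medians were then more than 1.5 times closer to 0, by up to 2.75 times. Percentiles belong to the medians of the measured differences, also where a median with bounds is given beside. Member counts are those of the main normalisation, and some members were under 1.5-fold without background correction. The clearest higher group was G2/M and mitosis, in which 26 of 27 measured genes were at least 1.5-fold higher and none lower, with a median of 1.21 (95% bootstrap interval over members 1.10 to 1.65) at percentile 100. Its members included the mitotic transcription factor FOXM1 (1.87), cyclin B1, CCNB1 (1.83), and the mitotic kinase AURKA (1.80). In G1/S and DNA replication, 5 of 23 genes were at least 1.5-fold higher and 1 lower, with a median of 0.42 (0.20 to 0.52), or 0.23 without background correction. Thymidylate synthase, TYMS (1.36), the polymerase subunit POLA1 (1.16) and the replicative helicase component CDC45 (1.16) were higher, and cyclin E1, CCNE1, read -0.88 (-0.36 without background correction).

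Among the lists of DNA repair, homologous recombination and the Fanconi pathway had 10 of 26 genes at least 1.5-fold higher and 1 lower, with a median of 0.54 (0.31 to 0.64) at percentile 100. The RecQ helicase BLM (1.37), FANCI (1.34), the exonuclease EXO1 (1.20) and RAD54L (0.91) were higher. Without background correction the median was 0.27, and BLM (0.56) and RAD54L (0.48) were under 1.5-fold. The cell cycle lists were also higher in this array, and whether the repair genes rose apart from them was not tested. Base excision and single-strand break repair had 7 of 21 genes higher and 0 lower, with a median of 0.29 (0.19 to 0.68) at percentile 98.1. The glycosylase NEIL3 (1.27) and the ligase LIG3 (1.03) were higher, at 0.48 and 0.63 without background correction. That list was no longer apart from random lists in the authors' processed values. Non-homologous end joining, with 2 of 11 genes higher and 0 lower, had a median of 0.02, and PRKDC (0.61) and XRCC6 (0.61) stood against PAXX (-0.56) and DCLRE1C (-0.55). PRKDC (0.54) and XRCC6 (0.58) were just under 1.5-fold without background correction. The probes of PRKDC differed in sign, and the list was apart from random lists in the authors' processed values only. Nucleotide excision and mismatch repair also had a median of 0.02, with 1 of 18 genes higher and 0 lower. DNA damage checkpoint genes had 5 of 17 higher and 0 lower, among them the phosphatase CDC25B (1.57), TOPBP1 (0.96), CDC25C (0.93) and the kinase CHEK1 (0.85), and the median of 0.28 lay at percentile 94.8, inside the range of random lists. CDC25C (0.42) and CHEK1 (0.49) were under 1.5-fold without background correction. The list median left that range with median scaling, with a detection p of 0.05, with no detection filter and with the mean over probes.

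NF-kB targets were the group furthest below the wild-type array. Of 20 measured genes, 17 were at least 1.5-fold lower and 0 higher, with a median of -2.11 (-2.86 to -1.05) at percentile 0, or -1.97 with the 10 genes detected in 1 array only set at their bound. The NF-kB subunits NFKB2 (-2.38) and RELB (-2.36) were lower, TNF was at least 4.79-fold lower, and the chemokines CXCL5 and CXCL1 were at least 5.39-fold and 4.49-fold lower. Without background correction these bounds were 2.08-fold for TNF, 2.25-fold for CXCL5 and just under 2-fold for CXCL1. The median was -1.20 without background correction and -0.93 without a detection filter, in both cases below the range of random lists. Of 8 measured leukocyte markers, 1 was at least 1.5-fold lower, the actin-bundling protein LCP1 (-2.49), and 0 were higher; the median of the 8 was -0.26, inside the range of random lists.

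Antigen presentation genes were lower in 12 of 17 cases and higher in 0, with a median of -0.82 (-1.25 to -0.32) at percentile 0, or -0.51 without background correction. These included the class I heavy chain HLA-B (-2.07), the peptide-loading factor TAPBP (-1.47) and the immunoproteasome subunit PSMB8, at least 3.69-fold lower (1.77-fold without background correction) and not detected in the adapted array. Interferon-stimulated genes had 15 of 29 members lower and 1 higher, with a median of -0.81 (-0.95 to 0.01), or -0.70 with bounds, at percentile 0. Without background correction the median was -0.29. IFITM1 (-2.23), IFITM3 (-1.39) and LGALS3BP (-1.23) were lower, and MX1 was at least 2.67-fold lower (1.48-fold without background correction). Values of the HLA and IFITM genes are uncertain because their sequences are close to one another.

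Extracellular matrix and collagen genes were lower in 14 of 28 cases and higher in 3, with a median of -0.74 (-1.24 to -0.10), or -0.60 with bounds, at percentile 0. The collagen VI chains COL6A1 (-2.69) and COL6A2 (-2.11) and the collagen COL18A1 (-2.10) were lower, whereas the proteoglycan decorin, DCN, was higher (1.97). Of 11 measured fibroblast markers, 6 of which the matrix list also holds, 3 were higher and 4 lower, with a median of -0.14. Matrix proteases and their inhibitors had 10 of 20 members lower and 1 higher, with a median of -0.64 (-0.83 to -0.49), or -0.57 with bounds, and the metalloprotease ADAM19 (-2.52) and the protease inhibitor SERPINE2 (-1.78) were lower, with cathepsin K, CTSK, higher (1.12). Cell adhesion and integrins had 8 of 20 lower and 1 higher, with a median of -0.58 (-0.71 to -0.43), or -0.55 with bounds, and ITGB5 at -1.52. The medians of these 3 lists were closer to 0 without background correction, at -0.35 for the matrix genes, -0.29 for the proteases and -0.23 for adhesion.

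Mesenchymal genes had 9 of 18 members lower and 1 higher, with a median of -0.61 (-1.29 to -0.13) at percentile 0, or -0.34 without background correction. Smooth muscle actin, ACTA2 (-1.82), tropomyosin TPM1 (-1.51), SPARC (-1.43) and the transcription factor SNAI2 (-1.41) were lower. Epithelial markers, with 7 measured, had 0 higher and 0 lower and a median of -0.07. Neural differentiation genes had 5 of 17 lower and 2 higher, with a median of -0.50 (-0.86 to -0.03), or -0.36 with bounds, at percentile 0.06. The GDNF-family receptor GFRA2 (-1.55), the growth cone protein GAP43 (-1.28) and TUBB3 (-1.15) were lower, and synaptophysin, SYP, was higher (1.21). The median of that list was -0.20 without background correction, and without a detection filter it was not apart from random lists.

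Immediate early and MAPK feedback genes had 10 of 20 members lower and 1 higher, with a median of -0.55 (-1.65 to -0.09) at percentile 0. JUN (-2.69) and the phosphatase DUSP1 (-1.88) were lower along with EGR1 and FOS. Genes of IGF signalling and receptor tyrosine kinases had 8 of 21 lower and 0 higher, with a median of -0.53 (-0.84 to -0.20), or -0.51 with bounds, at percentile 0.01, and -0.35 without background correction. The binding protein IGFBP3 (-1.82), ERBB3 (-1.23), EPHA2 (-1.21) and FGFR3 (-2.09) were lower, although the probes of FGFR3 differed in sign and ERBB3 read -0.52 without background correction.

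Hypoxia targets had 12 of 24 genes at least 1.5-fold higher and 4 lower, with a median of 0.48 (0.00 to 0.78) at percentile 100. The stress-induced mTOR regulator DDIT4 (1.56), the mitophagy receptor BNIP3 (1.33) and BHLHE40 (1.26) were higher. In the opposite direction, ANGPTL4 read -2.07, NDRG1 was at least 4.60-fold lower and the carbonic anhydrase CA12 at least 3.08-fold lower, bounds of 2.03-fold and 1.59-fold without background correction. Glycolysis genes had 8 of 18 higher and 1 lower, with a median of 0.44 (0.25 to 0.90), and beside ALDOC the hexokinase HK2 (1.25) and aldolase ALDOA (1.14) were higher while hexokinase HK1 was lower (-1.02). Cholesterol biosynthesis had 8 of 19 higher and 1 lower, with a median of 0.57 (0.23 to 0.85), or 0.30 without background correction, led by ACAT2 (1.49) and the isomerase IDI1 (1.41). Oxidative phosphorylation had 3 of 30 higher and 1 lower, with a median of 0.19 (0.09 to 0.28) at percentile 97.7. That call was lost with median scaling, in the authors' processed values, without a detection filter, with the mean over probes and against unmatched random lists.

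Genes of the unfolded protein and integrated stress response went both ways, with 7 of 29 higher, 7 lower and a median of 0.15, inside the range of random lists. The endoplasmic reticulum chaperone HSPA5 (-1.87) and the chaperone complex component SDF2L1 (-1.61) were lower, and the ATF4 target genes CHAC1 (1.28) and SESN2 (1.20) were higher. Heat shock proteins had 0 of 16 higher and 4 lower, with a median of 0.03.

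For the EWSR1-FLI1 program, FLI1 read 0.81, the surface antigen CD99 -0.55, the target transcription factor NKX2-2 -0.09 and STEAP1 0.35. Whether the FLI1 probe lies in the part kept in the fusion, and the level of NR0B1, were not analysed here. Activated targets had 7 of 36 higher and 4 lower, with a median of 0.02 at percentile 50, and the lipase LIPI (1.82) and the WNT antagonist DKK2 (1.20, or 0.49 without background correction) were among the higher ones. Repressed targets had 10 of 19 lower and 2 higher, with a median of -0.94 (-1.10 to -0.11), or -0.75 with bounds, at percentile 0. It was -0.36 without background correction and -0.57 with an offset of 50. The focal adhesion protein ZYX (-1.47), the matricellular protein CCN2 (-1.33) and the receptor TGFBR2 (-1.10) were lower.

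Pro-apoptotic genes had 4 of 22 lower and 1 higher, with a median of -0.27 (-0.51 to 0.13), or -0.10 with bounds, at percentile 1.81. BAX read -1.20 and BAD -1.15, and the 1 higher member was BNIP3 (1.33). BAD also lies in the run of lower genes on chromosome 11 given below. The median was -0.17 without background correction. That call was lost with median scaling, a detection p of 0.05, no detection filter, the mean over probes and with members detected in both arrays only. Anti-apoptotic genes had 2 of 12 higher and 0 lower, with a median of -0.04. NRF2 and glutathione genes (median -0.18, 17 measured), superoxide and peroxide scavengers (0.00, 18 measured), stem cell genes (-0.02, 18 measured), WNT and TGF-beta targets (-0.02, 19 measured), ABC transporters (-0.25, 11 measured) and cancer-testis antigens (0.36, 6 measured) also lay inside the range of random lists. Single members of these lists still differed, such as the methionine sulfoxide reductase MSRB3 (-2.31) and the secreted glycoprotein DKK3, at least 5.24-fold lower (2.21-fold without background correction).

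**Figure D2:**
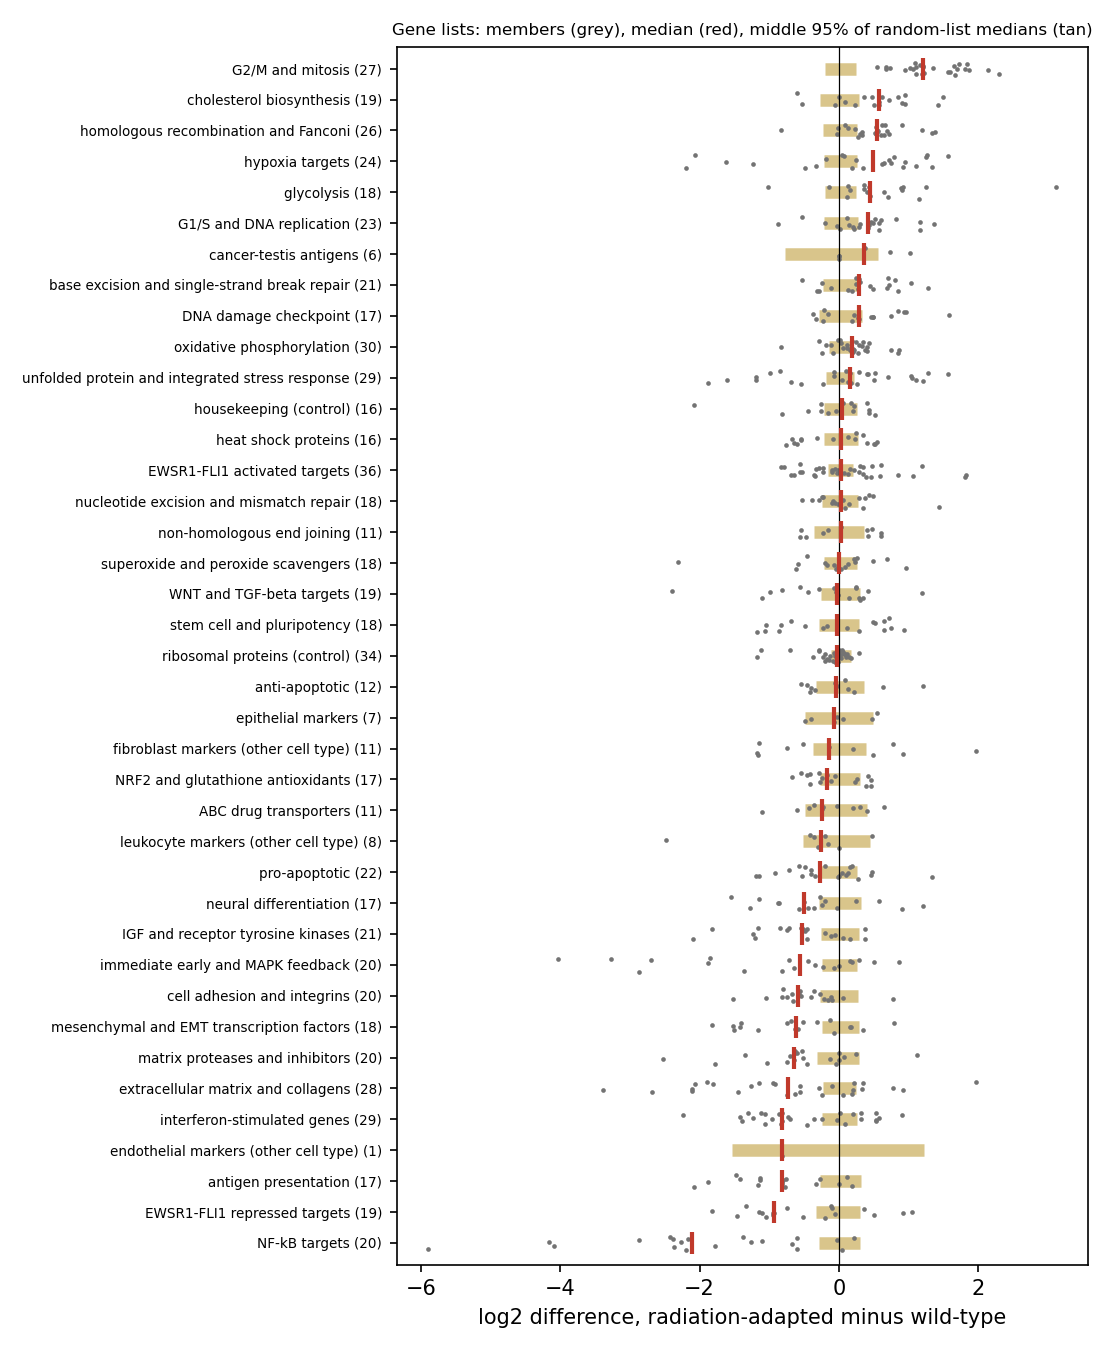
Log2 difference, radiation-adapted minus wild-type, for the measured members of the reported gene lists, whose numbers stand in brackets; grey points are genes, those detected in 1 array only drawn at their bound, red bars are list medians and tan bars the middle 95% of medians of 10000 random lists of matched expression. G2/M and mitosis lies furthest to the right with a median of 1.21 and NF-kB targets furthest to the left with -2.11. These medians use the measured differences, so they can differ from the median of the points drawn (-1.97 with bounds for NF-kB targets).

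Ribosomal protein genes, used as a control, had a median of -0.03 with 0 of 34 higher and 3 lower, and housekeeping genes had a median of 0.04 with 0 of 16 higher and 2 lower. The ribosomal median was -0.26 and outside the range of random lists with median scaling, and the housekeeping median was -0.05 in that setting. GUSB, often used as a reference gene, read -2.08. Of the endothelial markers 1 was detected, EGFL7 (-0.81), inside the range of random lists except without a detection filter. In the absence of replicates the only internal error was the scatter between probes of one gene, an SD of 0.28 per probe over 2326 genes, which leaves out variation between cultures. Of 126 genes at least 2-fold apart that had a second probe, 123 (97.6%) had the same sign in that probe.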

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

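The main comparison left out 17210 probes that carry no gene name or several. Of these, 3080 were detected in both arrays, and 149 were at least 2-fold apart, 79 of them higher and 70 lower in the adapted array. They are given here because they are a signal outside the named genes, and no explanation was tested.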

How the results depend on the processing

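The alternatives for chromosome 11 and for neighbouring genes were chosen after their values had been seen; the others were planned. No list apart from random lists and no named gene at least 1.5-fold apart changed sign. Without background correction, with an offset of 50 and in the authors' values, probes keep their ranks and the arrays are quantile-normalised. The sign of a probe is then all but fixed, so those settings say little about direction. Median scaling and the mean over probes could change signs. All 20 lists apart from random lists stayed so without background correction and with an offset of 50, and between 17 and 19 did elsewhere. Without background correction, which leaves differences of dim probes smaller, 76 genes were at least 2-fold higher and 153 lower, with 3 and 19 by bound. Of the 20 medians 14 were then more than 1.5 times closer to 0: 0.27 for homologous recombination, 0.23 for G1/S, 0.30 for cholesterol, -1.20 for NF-kB targets, -0.51 for antigen presentation, -0.29 for interferon, -0.35 for matrix, -0.29 for proteases, -0.23 for adhesion, -0.34 for mesenchymal, -0.20 for neural, -0.35 for IGF, -0.36 for EWSR1-FLI1 repressed and -0.17 for pro-apoptotic genes. Further medians were 0.94 for G2/M, -0.079 for leukocyte and -0.38 for endothelial markers, chromosome 11 was at -0.20 and the SD per probe was 0.189. An offset of 50 gave 163 higher and 267 lower, 9 and 47 by bound, and -0.57 for EWSR1-FLI1 repressed, -0.49 for proteases, -0.39 for adhesion, -0.60 for endothelial markers and -0.26 for chromosome 11. Median scaling gave 21 higher by bound, -0.72 for adhesion, -0.93 for endothelial markers and -0.26 for ribosomal proteins. The authors' values gave 463 higher and 537 lower, with 99 and 168 by bound. They gave -0.78 for adhesion, -1.03 for endothelial markers and an SD of 0.327. Without a detection filter, which lets in probes near background and allows no bounds, 395 genes were higher and 658 lower. Medians were then -0.93 for NF-kB targets, -0.10 for leukocyte and -0.13 for endothelial markers and -0.10 for chromosome 11. The mean over probes gave -0.77 for endothelial markers. Of 224 values of single genes, 136 moved without background correction, 77 with an offset of 50, 71 in the authors' values and 29 with the mean over probes. At 1.5-fold, 1194 were higher and 1168 lower, 132 and 205 by bound; higher genes were then 50.6% of those counted, against 40.4% at 2-fold. Where no reason is given, the cause was not tested. Signal over background limits dim genes: with 35.3% and 37.8% of probes detected, smaller differences of the rest were not detectable. No paired analysis was possible because each group has 1 array.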

Other observations

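The genes in this paragraph were chosen after their values were seen. On chromosome 4, 3 neighbouring measured genes that encode secreted proteins were all higher in the adapted array, the caseins CSN3 (2.42) and CSN1S1 (at least 3.64-fold) and FDCSP (at least 2.5-fold). The fatty acid desaturase SCD (1.66) and the lipogenic transcription factor SREBF1 (1.45) were higher, beside the cholesterol synthesis genes described above. The serine synthesis enzyme PHGDH (1.04) and the cysteine synthesis enzyme CTH (1.67) were higher. So were the kinesins KIF15 (1.80), KIF14 (1.74) and KIF23 (1.48) and POLQ (1.62), the polymerase of microhomology-mediated end joining, as single genes. In the MBD3L family 4 members were higher, MBD3L5 (2.97), MBD3L4 (1.48), MBD3L3 (at least 3.29-fold) and MBD3L2 (at least 2.23-fold), but their sequences are nearly identical. Among genes outside the lists, the lectin LGALS1 (-2.84), the surface protein CD24 (-2.47), the transcription factor CEBPD (-2.31) and the apolipoprotein APOE (-2.09) were lower, and the cell cycle kinase CDK6 was at least 7.08-fold lower and not detected in the adapted array. The detection p of CDK6 in that array was 0.013, so with the limit at 0.05 it counted as detected in both arrays. On chromosome 11, 7 neighbouring genes from NUDT22 to GPR137 were at least 1.5-fold lower. Such a run was met in 2 of 1000 shuffles of gene order, and in 1 with an offset of 50. It was met in 8 with the mean over probes, 11 with median scaling and 17 in the authors' values. Without background correction the run was 5 genes, met in 8 of 1000. Genes admitted at a detection p of 0.05 or with no detection filter broke it. The lowest window of 20 genes, on chromosome 7, had a median of -0.80, against -0.74 for the lowest in shuffles; with median scaling it no longer lay below all shuffles, and without background correction and with an offset of 50 the lowest was on chromosome 11. Windows of 50 genes on chromosomes 9 and 11 also lay below all shuffles, except on chromosome 11 with no detection filter. No window of 7 or 10 genes lay below all shuffles. The lowest medians were -1.40, against -1.77 in shuffles, and -1.01, against -1.22. Without background correction the bounds in this paragraph were smaller, at 1.69-fold for CSN1S1, 1.39-fold for FDCSP, 1.60-fold for MBD3L3, 1.32-fold for MBD3L2 and 2.73-fold for CDK6.

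Of the tests below, those of normalisation over all alternatives, of the median without listed genes and of gene length were set before their result was seen; all the others were chosen after. For the low NF-kB targets, the limit set in advance, a median below -1 under every alternative, was not met, since the median was -0.93 without a detection filter. Among the 4 alternatives that change the correction, scaling or source of the values, the value closest to 0 was -1.20. This subset was chosen after that limit had failed, and leaves out the setting that failed. All but median scaling keep the ranks of probes within each array, so they could shrink the median but hardly reverse it. The median thus stayed low under these 4, which does not decide whether processing contributed. Leukocytes in the wild-type culture stay open: 1 of 8 measured markers was at least 1.5-fold lower, but with 8 of 19 listed markers measured the limit of 10 could not be reached, and while no probe of PTPRC, TYROBP, LYZ or CD3E was detected in that array, all 8 measured markers were, with 1 of 2 probes of SPI1. The state of the cultures at harvest stays open and cannot be told apart from adaptation with 1 culture each, since the immediate early genes were also lower (median -0.55). Lower NF-kB activity in the adapted cells may be a biological source, a hypothesis that was not tested.

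On chromosome 8, 8 measured genes in a row were at least 1.5-fold higher with the main normalisation, from ENPP2 (1.57) through TAF2 (1.75), DSCC1 (1.48), DEPTOR (2.31), COL14A1 (at least 9.42-fold), MRPL13 (1.37) and MTBP (0.77) to SNTB1 (2.39). The 10 measured genes before had a median of 0.25 and the 10 after -0.21, although AARD (1.56) and MED30 (1.44) lay nearby with EXT1 (0.33), MAL2 (-1.02) and CCN3 (0.51) between. The longest such run in 1000 shuffles of gene order was 7, which argues against a chance order, although without background correction MTBP was at 0.41 and the run was 6 genes (4 in shuffles of those values), and 2 of 1000 shuffles met the run of 8 in the authors' values and at a detection p of 0.05. Windows of 7, 10 and 20 genes also had their highest medians on this chromosome (1.75, 1.53 and 0.71), above all shuffles. With 50 genes the highest lay on chromosome 2 (0.55), and windows on chromosomes 2 and 5 lay above all shuffles (0.44 at most). The shuffles move single genes, so they do not cover neighbours that vary together. Faulty single probes stay open, since only 2 further probes of these genes were detected, both of the 2 at least 1.5-fold higher; a copy gain of the segment in the adapted cells may be a source and was left open, the lowest of the 10 detected probes being at 0.77, because DNA was not analysed here.

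Of 23 chromosomes, 10 had a median outside the middle 95% of random lists, and chromosome 11 was the lowest, with a median of -0.32 over 661 genes and 75.8% of its genes below 0 against 47.7% elsewhere. Leaving out its 45 listed genes gave -0.32 over 616 genes but decides nothing, since leaving out any 45 could give at most -0.27; the share below 0 was 28.1 percentage points above that elsewhere, more than the 6.81% of its genes in the lists, which argues against a few listed genes as the cause. Random lists matched on gene length had medians down to -0.045 at the lower end of their middle 95%, which argues against length. All 4 parts of the chromosome in gene order were lower, the highest at -0.26, but the median was -0.20 without background correction and -0.10 without a detection filter. A loss of copies of chromosome 11 in the adapted cells may be a source, as a hypothesis that stays open because DNA was not analysed here.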
